A study of Rattus norvegicus with 8 samples.

How the data were processed

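RNA of rat abdominal aorta was profiled in 8 libraries, 4 after perivascular FeCl3 and 4 after saline, and per the labels the RNA was isolated with the mirVana kit and libraries were made from polyA RNA with the VAHTS Universal V6 kit. The deposited table holds 1 FPKM value per gene and library, computed by the authors; the submitters' processing notes name fastp, HISAT2, HTSeq and the rat genome build mRatBN7.2. Their versions, the annotation, the gene lengths and the harvest time were not given in the sources used here. Of 18090 rows 18073 were typed as protein coding and 17 had no type, and mitochondrially encoded genes were not analysed here. The labels put all libraries in 1 batch. Each column was matched to a sample by its title, and 0 value columns were left unmapped. Gene symbols were used as the table gives them, with older symbols for list members.

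FPKM values carry library totals and gene lengths, so that low values of a gene come in steps of 1 fragment. The total of each library and the length of each gene were recovered from these steps, and for 100% of the 18090 genes the values came out as whole fragments within a tolerance of 0.02. The recovered fragments summed to at least 99.97% of the recovered total in each library; 3 genes, Hbb among them, needed their count doubled to reach that sum, so their length is uncertain by that factor. On simulated data the recovery found the total of all 8 libraries exactly, and for 99.8% of 1975 genes the exact fragments in every library. Totals ranged from 24304434 to 30283292 fragments, and the median residual SD between samples of a group was 0.45 on the log2 scale. No pair of libraries was a duplicate, since at most 1.31% of genes present in both had the same number of fragments in any of 28 pairs. FPKM are not counts, and a count test on recovered fragments was used only as an alternative.

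The main test was fixed before the data were examined. Genes with FPKM of at least 1 in at least 4 of the 8 libraries were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (moderated test with a trend, two-sided), FeCl3 against saline, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change is on the log2(FPKM + 1) scale, which understates the change of low genes, and the fold threshold was 2. The 47 gene lists were compared by camera with a preset correlation of 0.01 among lists with at least 3 tested members, and again with an estimated correlation and with fry; 756 of 795 list entries were found in the table. Several lists share genes with each other, and many markers are also expressed by vessel wall cells. Library measures were compared by exact two-sided permutation tests in a family of 8.

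Genes were named by a rule fixed before the data were examined. It gives 14 genes always, then the 8 largest rises and falls among genes past the threshold (0 genes here), then up to 3 passing members of each list described or, where none passes, its most abundant member. Of these genes, 2 are not reported here. The 16 genes named at the end of the results were added after their values were seen, as were Col4a1, Col4a2, Adamts9, Cd79b and Fcrla.

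On simulated counts of the 11921 genes with the observed spread, 200 changed genes gave back 67% of the 4-fold and 91% of the 16-fold changes at the same threshold, with all calls of changed genes in the right direction, and 21 of 179 calls were false. With a smaller spread 98% and 100% were recovered, with 8 false calls among 206. For the lists, 1 simulated list of 44 was raised and found, and 1 other list was called. Both simulations drew each gene independently, whereas genes of the real lists had estimated correlations of up to 0.95 (B and plasma cell). They therefore do not measure how the tests behave on genes that move together. The alternatives covered pseudocounts of 0.1 and 0.01, other filters on low values, scaling to TPM, median-of-ratios scaling, quantile normalization, haemoglobin genes left out of the total, limma without trend, robust limma, array weights and each library left out. Chosen after seeing the data were limma voom on recovered fragments, a haemoglobin covariate, saline replicates 2 and 3 as the only controls, and camera over KEGG pathways of 10 to 300 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.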

Results

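The data were polyA RNA-seq profiles of abdominal aorta from wild-type rats. A filter paper carrying 10% iron chloride (FeCl3), a salt that injures the vessel wall and starts thrombosis, was laid around the vessel for 5 min in 4 samples, and 4 controls had 0.9% saline in its place. The samples of a condition were described as biologically independent. The comparison asked which transcripts differ between a vessel with FeCl3-induced thrombosis and a saline control. The time between exposure and harvest was not given in the sources used here. Values were FPKM (mapped fragments scaled by gene length and library total) for 18090 genes, and each library held 24304434 to 30283292 fragments by the totals recovered from the FPKM values.

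Gene lists of red cells, platelets and T and NK cells rose after FeCl3 in camera with its preset correlation, with median log2 fold changes of 3.48, 2.43 and 2.20 relative to all genes, but none of these lists passed with an estimated correlation (adjusted p = 0.389 for each). No individual gene passed the test. Haemoglobin genes took 23.8% ± 7.66 (SD, n = 4) of all fragments after FeCl3 and 5.22% ± 7.49 (SD, n = 4) after saline. The FeCl3 libraries ranged from 16.4% to 34.1%. Saline replicate 4, at 16.5%, lay within that range, and saline replicates 1, 2 and 3 held 1.63%, 1.30% and 1.49%. The difference of 18.6 percentage points had an exact two-sided permutation p of 0.0571 (adjusted p = 0.229 over 8 library measures), where 4 against 4 can reach 0.0286. Counting error was small beside this spread, with a 95% exact binomial interval of 16.4% to 16.5% for saline replicate 4, and such intervals cover counting error only.

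**Figure D1:**
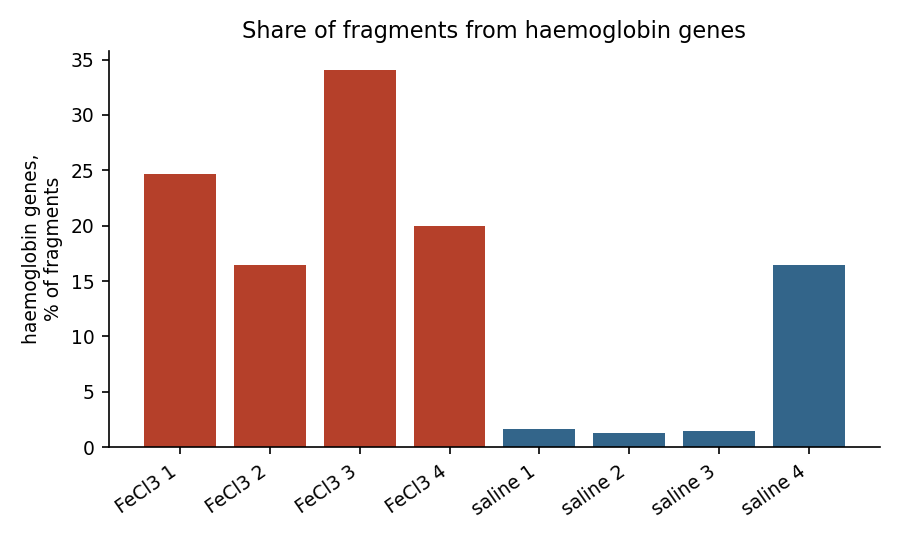
Bars give the percent of each library's fragments (y axis) that came from haemoglobin genes, with 1 bar per library (x axis), red for FeCl3 and blue for saline. The FeCl3 libraries sat between 16.4% and 34.1%, and saline replicate 4 at 16.5% lay apart from the other saline libraries, which stayed at or below 1.63%.

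Of 11921 genes tested with limma, 0 changed at a Benjamini-Hochberg adjusted p under 0.05, and the smallest adjusted p was 0.245. At an unadjusted p under 0.05 there were 1981 genes, 527 higher and 1454 lower after FeCl3, where 596 would be expected by chance. With a library left out this count ran from 1095 without saline replicate 3 to 2083 without saline replicate 1. It was 120 with a haemoglobin covariate, a fit chosen after seeing the data. limma voom on the recovered fragments, chosen after seeing the data, also called 0 genes and had 1605 at an unadjusted p under 0.05, 1089 higher and 516 lower. The balance of directions depended on scaling, as it also turned with median-of-ratios scaling (1162 higher, 473 lower) and quantile normalization (989 and 610). The FeCl3 and saline values did not overlap for 1169 genes, 9.81% of those tested against 2.86% by chance, with 126 higher and 1043 lower. With median-of-ratios scaling these were 554 and 395, with quantile normalization 434 and 429, and with FPKM rescaled to TPM 9 and 3964. The median log2 fold change of all tested genes was -0.25, and it was -0.90 with FPKM rescaled to TPM and -0.01 with median-of-ratios scaling. Medians of gene lists are therefore given relative to the median of all tested genes.

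The count of 0 rested on saline replicate 4. Without that library 160 genes changed (limma), 150 of them higher after FeCl3 and 10 lower, and 23 of the 160 belonged to the erythroid or platelet lists. Without saline replicate 4, Nfe2, a transcription factor of red cell and platelet precursors, had a log2 fold change of 4.15 (adjusted p = 0.00892), Hba-a1 4.18 (adjusted p = 0.0335) and Pf4 5.03 (adjusted p = 0.0115). This library had the highest Nfe2, Hba-a1 and Pf4 of the controls. Leaving it out favours a call of these genes, so these passes are not independent support. Nfe2 was also named after its values were seen. With any other single library left out, 0 genes changed. With saline replicates 1 and 4 both left out, a choice made after seeing the data, 51 genes changed, all higher, and all 51 were among the 160. Scaling to TPM called 3288 genes, 65 higher and 3223 lower, as haemoglobin genes made up 36.0% to 64.9% of the summed FPKM after FeCl3 and 4.58% to 43.6% after saline.

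Of 47 gene lists fixed before the data were examined, 44 had enough measured members, and 23 passed camera at its preset correlation, 20 higher and 3 lower after FeCl3. With an estimated correlation 0 lists passed in camera (2 at an unadjusted p under 0.05, smallest adjusted p = 0.389), and with fry, which asks another question, whether a list differs from no change and not from the other genes, 0 passed (3 at an unadjusted p under 0.05, smallest adjusted p = 0.426). With the haemoglobin level of each library as a covariate, a fit chosen after seeing the data, 8 lists passed, of which 2 were among the 23 (cytosolic ribosomal proteins, and T and NK cell). Of the others, oxidative phosphorylation (median 0.87), fatty acid oxidation (0.76) and glucocorticoid targets (0.53) were higher. Matrix proteins (-0.74), cell cycle (-0.73) and Schwann cell and nerve genes (-3.17) were lower. This covariate overlaps with the groups. With it the medians of 9 of the 20 higher lists were below 0: erythroid -0.21, platelet -0.45, B and plasma cell -0.21, leukocyte adhesion -0.16, complement -0.14, fibroblast -0.15, endothelium -0.13, lymphatic endothelium -0.07 and vasoprotective genes -0.18. Without the covariate, a count of at least 23 lists was reached in 10 of the 35 ways of splitting the 8 libraries into 4 and 4. Every statement below that a list rose or fell refers to camera with the preset correlation.

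**Figure D2:**
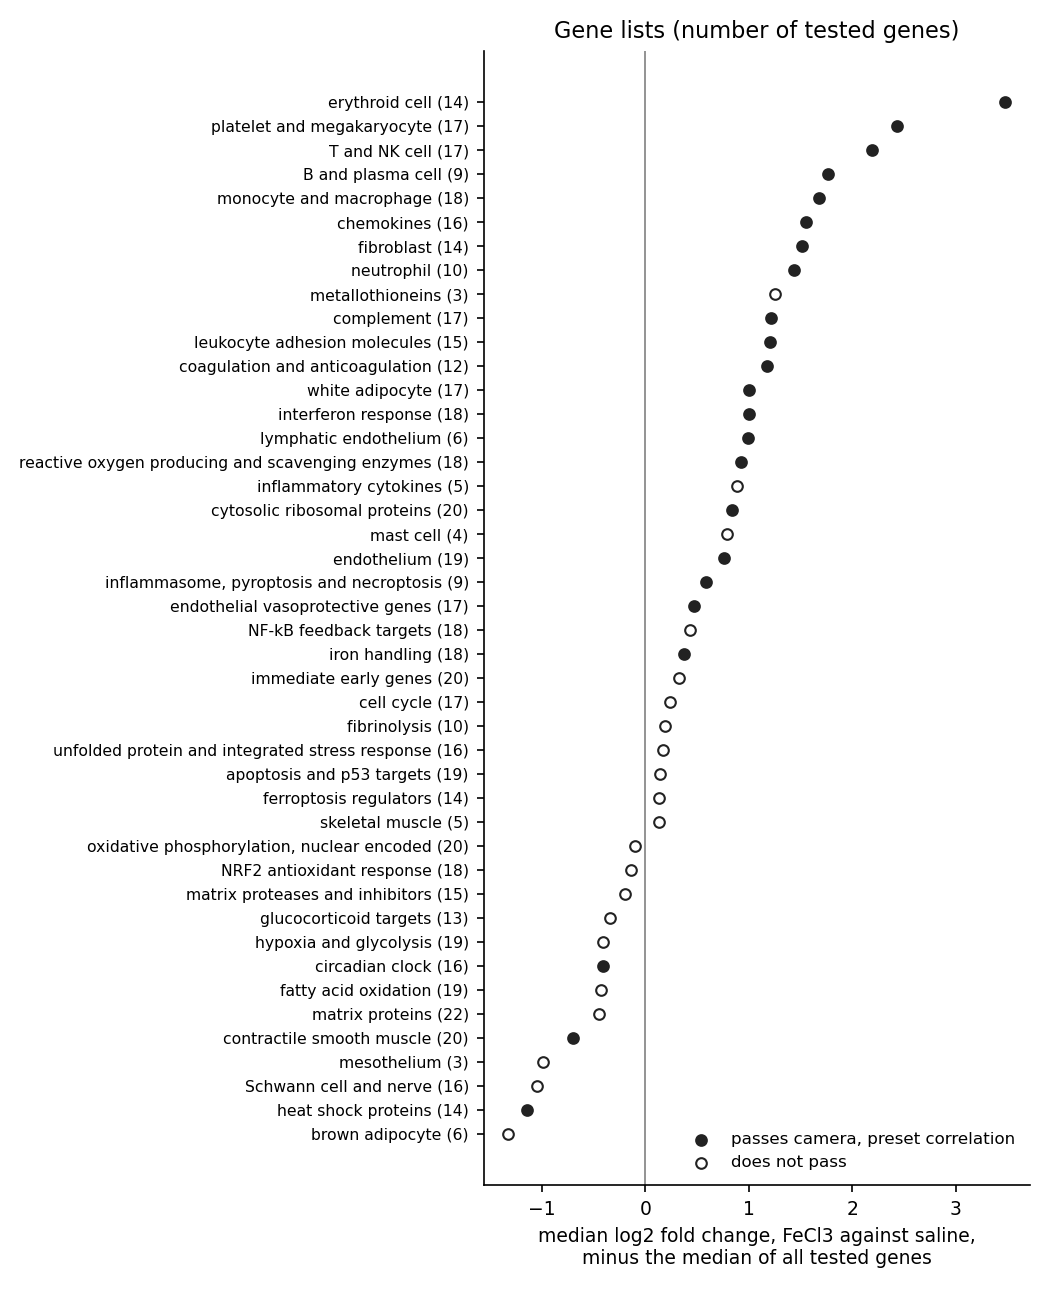
Each point is the median log2 fold change of a gene list, FeCl3 against saline, minus the median of all tested genes (x axis), for 44 lists (y axis, number of tested genes in brackets), filled where the list passed camera with the preset correlation. Erythroid genes sat highest at 3.48 and brown adipocyte genes lowest at -1.33, the latter not passing.

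Red cell and platelet transcripts rose as groups. All 14 erythroid genes had a positive fold change, with a median of 3.48 (camera adjusted p = 1.13e-15; adjusted p = 0.389 with an estimated correlation). Of these, 11 passed when adjusted over the list alone and 0 over all genes. Hba-a1, an alpha globin with near-identical copies among which reads can be split, had 262868 ± 114522 FPKM after FeCl3 and 47319 ± 67599 after saline (SD, n = 4 each; limma log2 fold change 3.32 ± 0.97 SE, adjusted p = 0.245). All 17 platelet and megakaryocyte genes were also positive, with a median of 2.43 (camera adjusted p = 4.00e-15; adjusted p = 0.389 with an estimated correlation), and 13 passed when adjusted over the list alone against 0 over all genes. Pf4, a chemokine stored in platelet granules, measured 1428 ± 686 FPKM after FeCl3 and 432 ± 766 after saline (SD, n = 4 each; log2 fold change 3.71 ± 1.21 SE, limma adjusted p = 0.251). Saline replicate 4 had 1579 FPKM of Pf4, within the FeCl3 range of 922 to 2429.

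White cell transcripts rose too. All 17 T and NK cell genes were positive, with a median of 2.20 (camera adjusted p = 9.40e-17; adjusted p = 0.389 with an estimated correlation), and all 17 passed when adjusted over the list alone, 0 over all genes. Cd3g, a chain of the T cell receptor complex, had 45.0 ± 59.8 FPKM after FeCl3 and 3.44 ± 4.57 after saline (SD, n = 4 each), and FeCl3 replicate 4 alone held 134 FPKM. The 9 B and plasma cell genes had a median of 1.77, with 3 passing when adjusted over the list alone (Cd79a, Cd79b and Fcrla) and 0 over all genes. Cd79a, part of the B cell receptor, had a log2 fold change of 2.78 ± 0.90 SE (limma adjusted p = 0.251). The 18 monocyte and macrophage genes and the 10 neutrophil genes were all positive, with medians of 1.68 and 1.44. Lyz2, a lysozyme of myeloid cells, measured 393 ± 202 and 126 ± 192 FPKM (SD, n = 4 each), and S100a8, a neutrophil calcium-binding protein, 49.6 ± 20.1 and 15.8 ± 22.7. With an estimated correlation the adjusted p = 0.389 for the B and plasma cell, monocyte and macrophage, and neutrophil lists. Saline replicate 4, the control with a high haemoglobin share, also stood above the other controls in these lists.

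**Figure D3:**
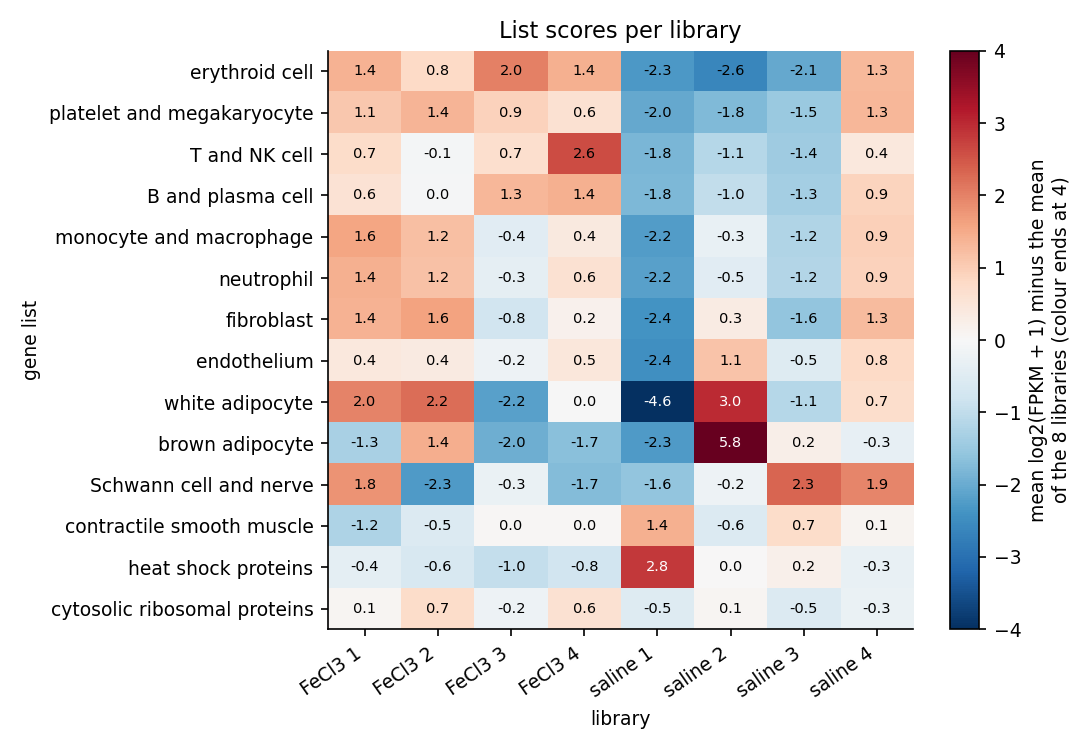
Each cell gives a library's mean log2(FPKM + 1) over a gene list minus the mean of the 8 libraries, with libraries on the x axis and 14 lists on the y axis, red above and blue below that mean. Saline replicate 4 was above the mean in the erythroid and platelet lists like the FeCl3 libraries, saline replicate 1 was high in heat shock proteins and low in most other cell types, and saline replicate 2 was high in adipocyte genes.

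Inflammatory and innate immune groups rose with the blood cell lists. Chemokines had a median of 1.56 (13 of 16 positive), leukocyte adhesion molecules 1.20 (13 of 15), complement 1.21 (15 of 17), interferon response genes 1.00 (18 of 18) and the inflammasome, pyroptosis and necroptosis list 0.58 (7 of 9). Camera adjusted p was 6.50e-07, 7.81e-06, 2.00e-05, 2.15e-09 and 0.00209 for these lists in that order. With an estimated correlation the complement list had an adjusted p = 0.480 and the other lists an adjusted p = 0.389. Of the 16 chemokine genes, 14 belong to the shortest quartile of gene lengths, whose median was 0.29 relative to all tested genes. Without saline replicate 1 the medians of the adhesion and interferon lists were 0.75 and 0.64. In all 5 lists the score of saline replicate 4 lay within the range of the FeCl3 libraries (3.98 in 3.55 to 4.42 for adhesion, 4.20 in 3.67 to 4.59 for interferon response), and saline replicate 1 had the lowest score (1.79 and 1.44). With the haemoglobin covariate the medians of the 5 lists were 0.50, -0.16, -0.14, 0.02 and 0.12, and none passed. No member passed over all genes or over its list alone. Ccl2, which attracts monocytes, had 34.5 ± 34.4 FPKM after FeCl3 and 4.77 ± 3.32 after saline (SD, n = 4 each; log2 fold change 2.51 ± 0.82 SE, limma adjusted p = 0.251), and Il1b 12.9 ± 4.86 and 4.43 ± 5.85 (log2 fold change 1.88 ± 0.67 SE, adjusted p = 0.258). Without saline replicate 4 Il1b passed, with a log2 fold change of 2.54 (limma adjusted p = 0.0422). That library had the highest Il1b of the controls, 13.1 FPKM, so leaving it out favours this call. Ccl6 had a log2 fold change of 2.83 ± 1.07 SE, Ifi27 0.72 ± 1.10 SE and Ninj1 0.05 ± 0.23 SE (limma adjusted p of 0.265, 0.752 and 0.921). Cfd (complement factor D), which is also in the white adipocyte list, had 2.76 ± 2.07 SE (limma adjusted p = 0.499). It measured 2771 FPKM in FeCl3 replicate 1, 33.9 in FeCl3 replicate 3, 768 in saline replicate 2 and 0 in saline replicate 1. Il6 and Sele lay below the filter on low values, with 3.86 ± 5.21 and 0.421 ± 0.351 FPKM after FeCl3 against 0.241 ± 0.122 and 0.408 ± 0.419 after saline (SD, n = 4 each). Selp, Icam1 and Vcam1, adhesion molecules of activated endothelium, had log2 fold changes of 0.63, 0.18 and 0.18 with limma adjusted p of 0.466, 0.731 and 0.816. With FPKM rescaled to TPM the fold changes of Icam1 and Vcam1 were -0.48 and -0.54, where the median of all tested genes was -0.90. The inflammatory cytokine list (5 genes tested, median 0.89) and the NF-kB feedback list (18 genes, median 0.43) did not pass, with camera adjusted p of 0.0578 and 0.120; the cytokine list passed without FeCl3 replicate 2 or saline replicate 4 (adjusted p of 0.0334 and 0.0112) and the NF-kB list without FeCl3 replicate 3 (0.0216). With a library left out their medians ran from 0.37 without saline replicate 1 to 1.35 without saline replicate 4, and from 0.19 without FeCl3 replicate 4 to 0.48 without FeCl3 replicate 2.

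The coagulation and anticoagulation list rose, with 9 of 12 genes positive and a median of 1.17 (camera adjusted p = 0.000358; adjusted p = 0.389 with an estimated correlation). Saline replicate 4 scored 3.93 in this list, within the FeCl3 range of 3.45 to 4.16, and saline replicate 1 scored 1.85, below the other saline libraries. With the haemoglobin covariate the median was 0.06 (camera adjusted p = 0.718). F3, tissue factor, which starts coagulation, had 92.8 ± 95.8 FPKM after FeCl3 and 27.9 ± 29.4 after saline (SD, n = 4 each; log2 fold change 2.00 ± 1.14 SE, limma adjusted p = 0.387). Vwf, the von Willebrand factor, had 23.1 ± 11.7 FPKM after FeCl3 and 9.43 ± 7.64 after saline (SD, n = 4 each; limma adjusted p = 0.319), and Thbd, thrombomodulin, had a log2 fold change of 0.65 ± 0.38 SE (adjusted p = 0.403). The fibrinolysis list did not pass (median 0.19, -0.02 to 0.32 with a library left out, camera adjusted p = 0.437).

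Of the lists that bear on iron and oxidative stress, enzymes that make or remove reactive oxygen species had a median of 0.92 with 12 of 18 genes positive, and the list rose (camera adjusted p = 8.08e-05; adjusted p = 0.389 with an estimated correlation). Saline replicate 4 scored 5.42 in this list, within the FeCl3 range of 4.73 to 5.98, and with the haemoglobin covariate the median was 0.28 (camera adjusted p = 0.245). Prdx2, a peroxidase that is also abundant in red cells, had 949 ± 367 FPKM after FeCl3 and 333 ± 254 after saline (SD, n = 4 each; log2 fold change 1.70 ± 0.52 SE, limma adjusted p = 0.248). Iron handling genes had a median of 0.38 (11 of 18 positive, camera adjusted p = 0.0316; adjusted p = 0.613 with an estimated correlation). The iron handling list did not pass without FeCl3 replicate 1, FeCl3 replicate 2, saline replicate 1 or saline replicate 3 (medians of 0.15, 0.33, 0.21 and 0.17; camera adjusted p of 0.125, 0.0684, 0.0984 and 0.106), and its median was 0.63 without FeCl3 replicate 3 and 0.57 without saline replicate 2. Saline replicate 4 scored 4.07 there, within the FeCl3 range of 3.33 to 4.32, and the median was 0.15 with the haemoglobin covariate (camera adjusted p = 0.488). Fth1, the ferritin heavy chain, had a log2 fold change of 1.02 ± 0.48 SE (limma adjusted p = 0.317). The NRF2 antioxidant list (median -0.14, 7 of 18 positive), ferroptosis regulators (0.14, 5 of 14) and metallothioneins (1.26, 2 of 3) did not pass, with camera adjusted p of 0.772, 0.283 and 0.0609, and their medians ran from -0.40 to 0.38, from -0.05 to 0.49 and from 1.00 to 1.75 with a library left out. Metallothioneins passed without FeCl3 replicate 2 or 3 (adjusted p of 0.0445 and 0.00118), and the NRF2 list's median was negative while its test pointed up. Hmox1, haem oxygenase 1, a target of NRF2, measured 3.02 ± 1.80 FPKM after FeCl3 and 3.64 ± 1.64 after saline (SD, n = 4 each; log2 fold change -0.26 ± 0.41 SE, limma adjusted p = 0.763). Txn1 and Mt2A had log2 fold changes of 0.23 and 1.01 (limma adjusted p of 0.756 and 0.379). With FPKM rescaled to TPM Txn1 lay at -0.51, where the median of all tested genes was -0.90.

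**Figure D4:**
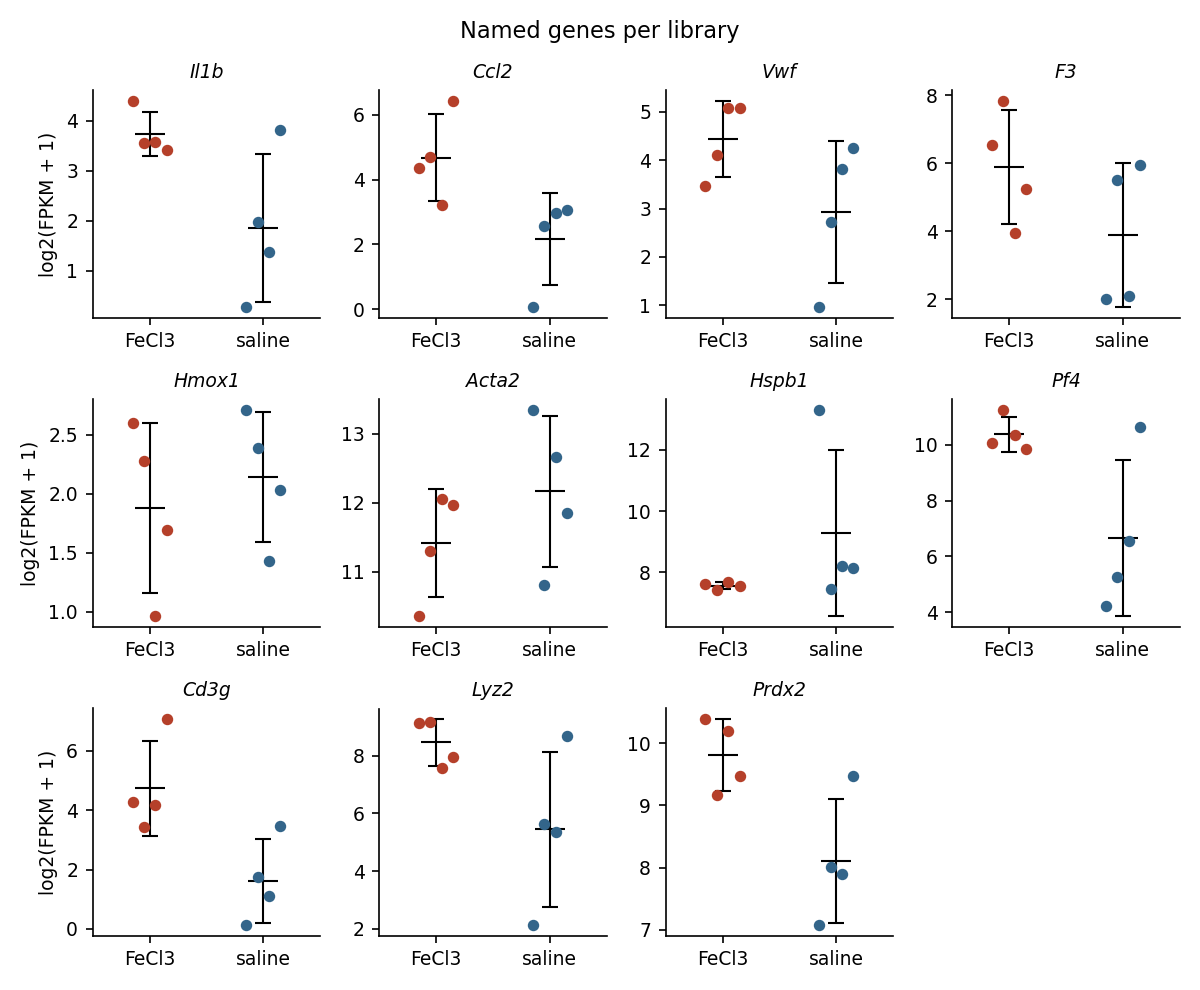
Points are log2(FPKM + 1) values (y axis) of 11 named genes in each library, red for FeCl3 and blue for saline (x axis), with the mean and SD (n = 4) as black bars; y axes do not start at 0. The groups of Ccl2 did not overlap, whereas those of Hmox1 and Acta2 did, and the high saline value of Hspb1 came from saline replicate 1.

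Contractile smooth muscle genes and heat shock proteins fell as groups, and both calls depended on saline replicate 1. All 20 smooth muscle genes had a negative fold change, with a median of -0.70 (camera adjusted p = 0.00383, and adjusted p = 0.661 with an estimated correlation). Of these, 10 belong to the longest quartile of gene lengths. The median log2 fold change of that quartile was -0.46 and that of all tested genes -0.25, both before any subtraction. Acta2, smooth muscle actin, had 3014 ± 1373 FPKM after FeCl3 and 5580 ± 3743 after saline (SD, n = 4 each; log2 fold change -0.75 ± 0.63 SE, limma adjusted p = 0.551), and Tagln had a log2 fold change of -0.49. All 14 heat shock genes were negative, with a median of -1.14 (camera adjusted p = 0.00587; adjusted p = 0.613 with an estimated correlation). Hspb1, a small heat shock protein, measured 10156 FPKM in saline replicate 1 and 172 to 291 in the other saline libraries, against 188 ± 15.3 after FeCl3 (SD, n = 4). Without saline replicate 1 the medians were -0.17 and -0.23 (camera adjusted p = 0.449 and 0.137); the smooth muscle list also missed the threshold without FeCl3 replicate 1 (median -0.35, adjusted p = 0.125). Circadian clock genes fell, with 15 of 16 negative and a median of -0.41 (camera adjusted p = 0.0316; adjusted p = 0.480 with an estimated correlation), and did not pass without FeCl3 replicate 4, saline replicate 1 or saline replicate 2 (adjusted p of 0.0694, 0.137 and 0.0817). Of the 16 clock genes, 7 belong to the longest quartile of gene lengths. Dbp, a clock output gene, had a log2 fold change of -0.63 (limma adjusted p = 0.739). Matrix proteins had a median of -0.45 with 20 of 22 negative and did not pass (camera adjusted p = 0.0642), but passed without FeCl3 replicate 2, FeCl3 replicate 3 or saline replicate 2 (adjusted p of 0.0147, 0.0113 and 5.26e-05). Its median was -0.15, -0.18 and -0.29 without FeCl3 replicate 1, saline replicate 1 and saline replicate 4 (adjusted p of 0.647, 0.737 and 0.225), and 0.19 with only saline replicates 2 and 3 as controls. It was -0.88 without saline replicate 2, and -0.74 with the haemoglobin covariate, where the list passed (camera adjusted p = 0.000425). Of the 22 matrix genes, 10 belong to the longest quartile of gene lengths. Col4a1 and Col4a2, basement membrane collagens, and Tnc passed when adjusted over the list alone (3 genes, 0 over all genes), as did the protease Adamts9 in the list of matrix proteases. Their log2 fold changes were -1.09, -1.19, -1.51 and -1.28, and like Cd79b and Fcrla these genes were named after their values were seen. Sparc, the most abundant matrix gene, had a log2 fold change of -0.44.

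Cell types of the vessel wall and its surroundings differed between libraries within a group. Fibroblast genes rose (14 of 14 positive, median 1.51, camera adjusted p = 1.48e-05; adjusted p = 0.480 with an estimated correlation), with a median of 0.87 without saline replicate 1, and saline replicate 4 scored 6.19, within the FeCl3 range of 4.14 to 6.53. Dcn, a proteoglycan of connective tissue, had a log2 fold change of 2.35 ± 1.21 SE (limma adjusted p = 0.349). Endothelial genes (14 of 19 positive, median 0.77), white adipocyte genes (14 of 17, 1.00) and endothelial vasoprotective genes (9 of 17, 0.48) rose, with camera adjusted p of 0.00260, 0.00477 and 0.0260, and adjusted p of 0.613, 0.661 and 0.480 with an estimated correlation. None of these 3 lists passed without saline replicate 1, in which endothelial and adipocyte transcripts were nearly lacking (medians of 0.24, 0.04 and 0.20; camera adjusted p of 0.134, 0.103 and 0.0511). The endothelial median was 1.29 without saline replicate 2 and 1.21 without saline replicate 4. The white adipocyte list also failed without FeCl3 replicate 2 (median 0.63, adjusted p = 0.0589), with medians of 0.66, 1.57 and 2.13 without FeCl3 replicate 1, FeCl3 replicate 3 and saline replicate 2. The vasoprotective list also failed without FeCl3 replicate 3 or saline replicate 3 (adjusted p of 0.0741 and 0.0563), with medians of 0.23 without saline replicate 3, 0.28 without FeCl3 replicate 4 and 0.42 without FeCl3 replicate 3. Pecam1, an endothelial adhesion molecule, had 4.58 FPKM in saline replicate 1 and 54.2 to 85.9 in the other saline libraries. Nos3, endothelial nitric oxide synthase, had a log2 fold change of 0.29 with all libraries and -0.44 without saline replicate 1 (limma adjusted p of 0.852 and 0.562), Ptgis -0.57 and Fabp4, a fatty acid carrier of adipocytes, 3.35. Lymphatic endothelial genes (4 of 6 positive, median 0.99, with Ccl21 at 2.29) rose at a camera adjusted p of 0.0446 (adjusted p = 0.613 with an estimated correlation) and did not pass without FeCl3 replicate 1, FeCl3 replicate 2, saline replicate 1 or saline replicate 3 (adjusted p of 0.156, 0.0589, 0.120 and 0.106).

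Cytosolic ribosomal protein genes rose, with all 20 positive and a median of 0.84 (camera adjusted p = 1.48e-12; adjusted p = 0.389 with an estimated correlation), and Rps14 had 1504 ± 603 FPKM after FeCl3 and 876 ± 135 after saline (SD, n = 4 each; log2 fold change 0.71 ± 0.34 SE, limma adjusted p = 0.321). With FPKM rescaled to TPM the log2 fold change of Rps14 was -0.03, where the median of all tested genes was -0.90. All 20 genes belong to the shortest quartile of gene lengths, whose median over all genes was 0.29 relative to all tested genes, and the log2 fold change went down with gene length across all genes (Spearman's rho of -0.40). Brown adipocyte genes (median -1.33, -2.12 to 0.20 with a library left out, camera adjusted p = 0.587) and Schwann cell and nerve genes (-1.05, -2.04 to -0.35, adjusted p = 0.232) did not pass; Ucp1, the uncoupling protein of brown fat, measured 6272 FPKM in saline replicate 2. The remaining lists also did not pass with all libraries in the fit without a covariate. Some of these passed with a library left out, namely immediate early genes without FeCl3 replicate 2 or saline replicate 1 (camera adjusted p of 0.000173 and 0.00180), cell cycle without FeCl3 replicate 2 or saline replicate 4 (0.0133 and 0.00230) and oxidative phosphorylation without saline replicate 2 (0.00510), as did Schwann cell and nerve genes without FeCl3 replicate 1 (0.00248). Medians, with their range when a library was left out in brackets, were 0.32 for immediate early genes (0.15 to 0.67), 0.24 for cell cycle (0.11 to 0.59), 0.79 for mast cells (0.42 to 1.11), 0.13 for skeletal muscle (-0.29 to 0.41), 0.17 for the unfolded protein response (0.05 to 0.23), 0.14 for apoptosis and p53 targets (0.05 to 0.16), -0.41 for hypoxia and glycolysis (-0.57 to -0.07), -0.10 for nuclear-encoded oxidative phosphorylation (-0.49 to 0.40), -0.43 for fatty acid oxidation (-0.80 to 0.45), -0.34 for glucocorticoid targets (-0.65 to 0.06), -0.20 for matrix proteases (-0.25 to 0.00) and -0.99 for mesothelium (-1.50 to 0.20). The positive ends for oxidative phosphorylation, fatty acid oxidation and mesothelium came without saline replicate 2, that for glucocorticoid targets without saline replicate 1, and skeletal muscle was negative without FeCl3 replicate 1, FeCl3 replicate 3 or saline replicate 3. The oxidative phosphorylation and matrix protease medians were negative while their tests pointed up. Of the liver list 2 genes were tested and of the kidney and adrenal list 0, and no mitochondrially encoded transcript was among the genes analysed, so these lists have no test.

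A further 16 genes were chosen after their values were seen. They were the 8 largest rises and the 8 largest falls among genes that met 3 criteria. These were an unadjusted limma p under 0.01, groups that did not overlap and a mean of at least 5 FPKM in the higher group. Placeholder symbols, such as those starting with LOC or RGD, were left out. On the higher side these were Lgals5, Slpi, Lyl1, Nfe2, Cd53, Ms4a6bl, Tspan33 and Slc38a5, with log2 fold changes from 2.58 for Slc38a5 to 3.98 for Lgals5. On the lower side they were Flnc, Sdc4, Dst, Col16a1, Tnc, Cpxm2, Zbed6 and Lamc1, with log2 fold changes from -2.02 for Flnc to -1.44 for Lamc1. Each had a limma adjusted p of 0.245. Lamc1, a laminin chain of basement membranes, measured 38.2 ± 3.03 FPKM after FeCl3 and 120 ± 74.2 after saline, and Nfe2 measured 35.5 ± 11.7 and 6.52 ± 11.1 (SD, n = 4 each). The longest quartile of gene lengths held 759 of the 1454 genes lower at an unadjusted p under 0.05. The falls named here were not adjusted for gene length.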

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

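All tests of an explanation in this part were chosen after the results they bear on were seen. A library was singled out where its gap to the nearest other library of its group, divided by the range of the group, exceeded Dixon's 95% critical value for 4 samples. Of 210 groups of 4 examined, 19 did so, where chance would give about 10.5, and the measures overlap in genes.

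Saline replicate 4 stood above the other saline libraries in the haemoglobin share (gap of 0.979 of the range, 16.5% against 1.30% to 1.63%), the erythroid score (0.861), the platelet and megakaryocyte score (0.838), Hba-a1 (0.881), Lyl1 (0.889) and Nfe2 (0.890). For the rise of blood cell lists after FeCl3, blood transcripts present only after FeCl3 were argued against, since haemoglobin genes took at least 1.30% of fragments in each of the 4 saline libraries. Blood of a single makeup present in differing amounts stays open, since the platelet score minus the erythroid score differed by -0.84 between the groups with an exact permutation p of 0.0857. This test cannot decide, because platelet scores in saline replicates 1, 2 and 3 were low (1.01, 1.28 and 1.55). At such values log2(FPKM + 1) understates change, so a negative difference can arise without a difference in makeup. Of 45 list scores of saline replicate 4, 35 lay within the range of the 4 FeCl3 libraries and 21 within that of the 3 other saline libraries, 19 in the former alone and 5 in the latter alone; it lay outside the FeCl3 range, among others, in matrix proteins (7.82 against 6.18 to 7.24), heat shock proteins (5.61 against 4.95 to 5.53), circadian clock (3.13 against 1.87 to 3.03) and ribosomal proteins (9.05 against 9.13 to 10.1). Clot or leukocytes held by the injured vessel, residual blood from dissection and a mislabelled control stay open, because nothing in the design separates them.

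Saline replicate 1 stood above the other saline libraries in the heat shock score (gap of 0.833 of the range), Hspb1 (0.872) and Tnc (0.875), and below them in Ccl2 (0.836) and Pecam1 (0.835). A candidate explanation for most of the lower heat shock proteins after FeCl3 is the state of this library, since without it the list's median was -0.23 relative to all genes (camera adjusted p = 0.137), where it was -1.14 with all libraries. A smaller effect of FeCl3 stays open, as the other saline libraries scored 5.61 to 6.12 and the FeCl3 libraries 4.95 to 5.53. What set this library apart was not given in the sources used here.

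In the FeCl3 group, replicate 1 lay below the others in matrix proteins (gap of 0.840 of the range) and above them in skeletal muscle genes (0.830). Replicate 3 lay below the others in the endothelium score (0.849) and in Mt2A (0.851). Replicate 2 lay above the others in Txn1 (0.869) and Ucp1 (0.944) and below them in Tnc (0.835). Saline replicate 2 lay above the other saline libraries in the mesothelium score (0.868).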

How the results depend on the processing

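The fits with voom, with a haemoglobin covariate and with only saline replicates 2 and 3 as controls were chosen after seeing the data. The count of 0 changed genes held under every other setting except TPM scaling (3288 genes, 65 higher, 3223 lower, 3147 at least 2-fold), which divides all genes by a total of which haemoglobin makes up 4.58% to 64.9%, only saline replicates 2 and 3 as controls (51, all 51 higher and at least 2-fold) and the fits without a library, which ran from 0 to 160 (0 to 150 higher, 0 to 10 lower, 0 to 160 at least 2-fold), the 160 without saline replicate 4. The cause was not tested further. The 23 lists became 0 with an estimated correlation and 0 with fry, both of which allow for the correlation among genes of a list, while fry tests against no change and camera against the other genes; other settings gave 21 to 24 lists and the fits without a library 16 to 25. With the haemoglobin covariate, which overlaps with the groups, 8 lists passed, of which 2 were among the 23 (cytosolic ribosomal proteins, and T and NK cell). Of the 23 lists, 15 passed with each library left out in turn. KEGG pathways numbered 64 without saline replicate 1, 64 with only saline replicates 2 and 3 as controls and 0 with an estimated correlation. The planned fits on count tables were not run, as only FPKM were used here; voom used the fragments recovered from the FPKM values. No paired analysis was possible because the sample titles of the groups share only 1 number. Among 57 tested named genes, 1171 of 1251 values under alternatives kept their direction and side of the threshold, 42 passed in addition and 38 changed sign; for the lists 839 of 1052 kept both, 37 passed in addition, 108 no longer passed and 68 changed direction in the test. Quantile normalization gives the most abundant gene a fixed value, so Hba-a1 has 0 there. For other changes of direction the cause was not tested, and the log2 fold changes follow. For lists these are medians before subtracting the median of all genes. A list is given here where the direction of its test changed, so its median can keep the sign it had with all libraries. Fry and camera differ by construction. With no filter on low values: NRF2 antioxidant response -0.32, mesothelium -0.39. With median-of-ratios scaling: NRF2 antioxidant response -0.16, oxidative phosphorylation -0.058, matrix proteases and inhibitors -0.20. With quantile normalization: NRF2 antioxidant response -0.39, oxidative phosphorylation -0.24, matrix proteases and inhibitors -0.30, Txn1 -0.12, Hba-a1 0. With voom on recovered fragments: NRF2 antioxidant response -0.15, oxidative phosphorylation -0.069, Hmox1 0.067. With only saline replicates 2 and 3 as controls: NRF2 antioxidant response -0.78, oxidative phosphorylation -1.15, matrix proteins -0.20, glucocorticoid targets -0.47, Nos3 -0.43, Ifi27 -0.45, Sparc 0.082. With fry: NRF2 antioxidant response -0.39, ferroptosis regulators -0.11, unfolded protein and integrated stress response -0.075, fibrinolysis -0.060, apoptosis and p53 targets -0.10, oxidative phosphorylation -0.35, matrix proteases and inhibitors -0.45. With globin covariate: inflammatory cytokines -0.46, leukocyte adhesion molecules -0.32, complement -0.30, hypoxia and glycolysis 0.18, fatty acid oxidation 0.61, matrix proteases and inhibitors -0.44, cell cycle -0.88, glucocorticoid targets 0.37, lymphatic endothelium -0.22, fibroblast -0.31, mesothelium 0.13, brown adipocyte 0.35, B and plasma cell -0.37, mast cell -0.59, platelet and megakaryocyte -0.61, erythroid cell -0.36, Hmox1 0.042, Il1b -0.25, Selp -0.70, Icam1 -0.34, Nos3 -0.37, Ifi27 -0.11, Ccl21 -0.81, Ucp1 0.11, S100a8 -0.086, Lyz2 -0.19, Cd79a -0.37, Pf4 -0.51, Cd79b -0.15, Fcrla -0.26. With TPM scaling, where the median of all tested genes was -0.90: fatty acid oxidation -1.40, glucocorticoid targets -1.31, mesothelium -1.89, brown adipocyte -2.14, Icam1 -0.48, Vcam1 -0.54, Thbd -0.058, Nos3 -0.21, Txn1 -0.51, Ninj1 -0.68, Rps14 -0.026. With array weights: fatty acid oxidation -0.40, matrix proteases and inhibitors -0.42, cell cycle -0.31, glucocorticoid targets -0.23, mesothelium -0.59, Nos3 -0.13, Ifi27 -0.016. With filter of 5 FPKM: matrix proteases and inhibitors -0.54, cell cycle -0.30. With a library left out: NRF2 antioxidant response -0.73 to 0.20, unfolded protein and integrated stress response -0.16 to 0.0058, oxidative phosphorylation -0.76 to 0.23, fatty acid oxidation -1.13 to 0.28, matrix proteases and inhibitors -0.47 to -0.25, glucocorticoid targets -0.91 to -0.27, mesothelium -1.75 to 0.024, brown adipocyte -2.45 to 0.025, Hmox1 -0.50 to 0.049, Vcam1 -0.14 to 0.40, Nos3 -0.44 to 0.79, Txn1 -0.076 to 0.37, Ifi27 -0.50 to 1.30, Ninj1 -0.074 to 0.13, Dbp -1.26 to 0.053.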

Other observations

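The tests of KEGG pathways and of the splits of the libraries were chosen after the results they bear on were seen; the test on gene length among smooth muscle and matrix genes was written before its result was seen.

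Among 310 KEGG pathways, 108 passed camera with the preset correlation, 48 higher and 60 lower after FeCl3, and 0 passed with an estimated correlation (smallest adjusted p = 0.999). The Ribosome pathway (152 genes, median 0.80 relative to all genes) and Hematopoietic cell lineage (66 genes, 1.34) were on the higher side. Focal adhesion (164 genes, -0.32), the contacts of cells with their matrix, and the Hippo signaling pathway (113 genes, -0.21) were on the lower side. Among pathways near the lists described, those that passed included Complement and coagulation cascades (43 genes, 0.89), Natural killer cell mediated cytotoxicity (92 genes, 0.51), Cytokine-cytokine receptor interaction (123 genes, 0.48), Cell adhesion molecules (110 genes, 0.39), Ferroptosis (38 genes, 0.24), NF-kappa B signaling pathway (84 genes, 0.23) and, lower, Circadian rhythm (30 genes, -0.22). Those that did not pass included ECM-receptor interaction (67 genes, -0.54, adjusted p = 0.0723), Vascular smooth muscle contraction (97 genes, -0.28, 0.104), Platelet activation (101 genes, -0.11, adjusted p = 0.646), Chemokine signaling pathway (134 genes, 0.0044, 0.150), Leukocyte transendothelial migration (87 genes, -0.0049, 0.349) and TNF signaling pathway (90 genes, -0.022, 0.828). Without saline replicate 1 the count was 64.

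Regrouping the libraries did not exclude chance for the counts of lists or pathways. A count of at least 23 lists was reached in 10 of 35 splits of the 8 libraries, with 30 in the highest other split, and a count of at least 108 pathways in 5 of 35, with 126 in the highest other. The 1981 genes at an unadjusted p under 0.05 were reached by 1 of 35 splits, the real one and the smallest share possible here, with 1872 in the highest other; as 1 of 4 counts examined after the results were seen, this is weak evidence against chance. For genes past the adjusted threshold the splits decide nothing, since the count of 0 (limma; 0 also with voom) is met by all 35. The highest other split called 95 genes, with FeCl3 replicate 1 and saline replicates 2, 3 and 4 on the same side, and was also the one with 1872, so the samples hold a structure besides the groups.

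Long genes had lower fold changes than short genes. Spearman's rho of the log2 fold change with the recovered gene length was -0.40 across 11921 genes, which are not independent replicates, and the median log2 fold change went from 0.04 in the shortest quartile to -0.46 in the longest, which held 759 of the 1454 genes lower at an unadjusted p under 0.05. Short transcripts brought by blood cells as the whole cause were argued against only for 42 smooth muscle and matrix genes. Among these rho was -0.46 (permutation p = 0.00295), and it stayed between -0.47 and -0.31 with each library left out. The permutation shuffled genes, which move together, so its p does not measure the spread between libraries. Shorter RNA fragments in some of the FeCl3 libraries may contribute, since they predict that same rho of -0.46, but the libraries were uneven. Over all genes, rho of a library's deviation with length ran from -0.49 to -0.0050 after FeCl3 and from -0.044 to 0.30 after saline. Among the smooth muscle and matrix genes it ran from -0.44 to 0.033 and from 0.045 to 0.26. FeCl3 replicates 3 and 4 had -0.44 and -0.32 in these genes but -0.097 and -0.0050 over all genes. FeCl3 replicates 1 and 2 had 0.033 and -0.19 in these genes but -0.20 and -0.49 over all genes. The 42 genes therefore do not decide the cause of the trend over all genes, be it blood or fragment length. A lower level of long muscle and matrix transcripts after FeCl3 stays open, as untested, and RNA integrity was not given in the sources used here.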
